A study of Homo sapiens with 2 samples.

How the data were processed

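Single-cell RNA, surface protein and hashtag counts were analysed for 1 donor sample that holds both NK cell cultures. Per the labels' protocols, NK cells were isolated from donor blood, cultured into control and memory-like cells and run on the 10x Genomics 5′ V(D)J kit with feature barcoding for TotalSeq-C antibodies. The deposited matrices hold whole-number UMI counts per feature and barcode, not normalized. Per the file headers they were written by Cell Ranger 3.0.1. Per the submitters' processing notes, Cell Ranger 3.0.1, Cell Ranger 3.0 and Seurat were used with GRCh38 and mm10; what Seurat was used for is not given in the sources used here. Per the file headers and feature tables, each matrix has 6456 barcodes and 64591 gene features (33538 human and 31053 mouse), and gene names were used as those tables pair them with Ensembl identifiers. One matrix adds 26 antibodies and the other 2 hashtags. Barcodes and genes were in the same places in both, with 0 differing gene entries, so the matrices were used as 1 sample with gene counts from the surface protein matrix.

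Groups were made from the hashtag counts and named by hashtag. Hashtag_1 held 28.6% and Hashtag_2 71.4% of hashtag UMIs. HTODemux of Seurat 5.3.0 in R 4.3.3 was run on centred log-ratio values with a positive quantile of 0.99, which set thresholds of 488 UMIs for Hashtag_1 and 998 for Hashtag_2; 3 barcodes were called Hashtag_1 at or below its threshold, and 0 for Hashtag_2. Barcodes with at least 500 human genes, at most 10% mitochondrial UMIs and 1 hashtag were kept. The filter left 5566 barcodes, of which 1810 were Hashtag_1, 1966 Hashtag_2, 266 doublets of both hashtags and 1524 without a called hashtag. Doublets of both hashtags were removed. Doublets within a hashtag were sought with Scrublet, run in Scanpy 1.11.5, which marked 0 of 5566 barcodes and so did not work here; these doublets remain in the data. Their number was not estimated, and removal of the 5% of cells with the highest scores was tried instead.

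UMIs of human genes were summed per hashtag and expressed as CPM. Genes tied to sex were left out of the counts of genes. Ratios are of CPM, log2 ratios have 1 CPM added to both sides, and a gene counted as higher where the ratio was at least 1.5 and the higher group had at least 10 CPM. A group at 0 was set to 3 UMIs, which is 0.232 CPM in Hashtag_1 and 0.0928 CPM in Hashtag_2. Sums have exact Poisson 95% intervals, ratios an exact interval conditional on the sum of both counts, and shares exact Clopper-Pearson intervals (SciPy 1.17.1). Intervals and floors cover counting error only. With 1 library, no p-value or standard error was computed. The hashtag calling, cell filter, size limits, gene lists, cell type markers, rule for named genes and most alternatives were set before the data were examined.

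Named genes were the 12 with the largest log2 ratio in each direction among 3258 genes at 50 CPM or more that were not mitochondrial, ribosomal, immunoglobulin or T cell receptor variable genes or genes tied to sex, the 3 largest of each of 24 gene lists, and 10 fixed genes, giving 89 genes. An HLA gene whose presence differs between people was left out of the text although the rule named it, and 2 further genes that the rule named are not reported here. Genes of near-identical families (KIR, CCL3 and CCL4, HLA, XCL1 and XCL2) are uncertain, since the treatment of reads shared by copies is not given in the sources used here. KLRK1, KLRD1 and CD94 were named after their values were seen, as were the genes of cluster 8 other than HBB. Named proteins were the 6 with the largest ratio in each direction, with CD56, CD16, NKG2A and CD25; 1 further planned protein, CD69, was not in the panel.

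The gene lists covered activating receptors, inhibitory and checkpoint receptors, cytotoxic effectors, cytokines, cytokine receptors, JAK-STAT feedback, transcription factors, the TNF family, CD56bright and CD56dim genes, homing, S phase, G2 and mitosis, glycolysis, oxidative phosphorylation, amino acid metabolism, cholesterol synthesis, interferon-stimulated genes, MHC class II, MHC class I, survival, stress and immediate early genes, the unfolded protein response and the cytoskeleton. A list's median log2 ratio over members at 10 CPM or more was set against 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries.

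The ratio and list steps were tested on simulated data drawn from the real means and depths over 8077 genes. Simulated folds of 2, 4 and 0.25 passed 1.5 times in 100% of genes and a fold of 0.5 in 97.0%, while folds of 1.25 and 0.8 passed in 0%. Of 7956 unchanged genes, 0% passed, and 95.6% of their intervals held the true ratio. The counts were Poisson draws, so this checks the computation and not how real UMIs clump in single cells. A planted list reached percentile 100, and 4 of 100 unchanged lists fell outside the middle 95%. These lists were independently drawn genes, so this rate need not hold for genes that vary together.

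Proteins were compared as mean antibody UMIs per cell, scaled by total antibody UMIs (means of 7107 and 7773 per cell), and counted as higher at a ratio of at least 1.5. The background was the 99th percentile of the highest isotype control per cell, 49 UMIs in Hashtag_1 and 73 in Hashtag_2. Shares of cells with a UMI were taken after thinning to 2724 UMIs, the 10th percentile of the shallower group. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.6. A cluster was named where at least 3 markers of 8 marker lists were detected in at least 25% of its cells and its leading genes did not go against the name. A cluster with a median UMI count under 1/3 of that of the kept cells and no NK marker in its top 10 genes stayed unnamed, which applied to cluster 7; clusters 3 and 8 were left unnamed after their genes were seen, cluster 3 because its top 10 genes held more innate lymphoid than NK markers. No cluster had an NK marker among its top 10 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

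Alternatives were TMM scaling (edgeR 4.0.16), totals without mitochondrial and ribosomal protein genes, equal weight per cell, MULTIseqDemux, a margin rule (at least 90% of hashtag UMIs and 20 UMIs from one hashtag), no cell filter, a stricter filter (1000 genes, 5% mitochondrial), thinning, omission of unnamed clusters and of Scrublet calls, the other matrix's gene counts, a minimum of 50 CPM or none, pseudocounts of 0.1 and 10 CPM, other scalings of proteins and other resolutions (0.3 and 1.0). Chosen after seeing the data were unscaled UMIs per cell, omission of barcodes with 5% or more mouse UMIs, of 4 clusters led by cell cycle or histone genes, of clusters 7 and 8 alone and of the highest Scrublet scores, use of only those barcodes that HTODemux called negative, and the share of cells above the isotype background. The negative barcodes were split into groups by MULTIseqDemux.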

Results

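Natural killer (NK) cells, lymphocytes that kill infected or transformed cells, were taken from the blood of 1 normal donor and grown, per the labels, into a control culture and a cytokine-induced memory-like culture. Memory-like NK cells are cells briefly exposed to activating cytokines that later respond more strongly on restimulation. The cells were labelled with 2 hashtags, antibodies with a DNA tag that marks a group of cells, and with a panel of 26 antibody tags, 3 of them isotype controls that bind no known target. Messenger RNA and tags were counted per cell barcode as unique molecular identifiers (UMIs). The 2 deposited samples hold surface protein tags in one and hashtags in the other, beside the gene counts. They hold the same 6456 barcodes, and 0 of their gene counts differ, so they were counted as 1 sample. Gene UMIs summed to 60043902, of which 59068413 were from human and 975489 from mouse genes. Antibody UMIs summed to 38394829 and hashtag UMIs to 12650986. The hashtags are named Hashtag_1 and Hashtag_2, and no source used here states which culture each one marked, so neither is called control or memory-like; that each marked 1 culture is assumed. All values below compare the cells of one hashtag with those of the other, in 1 library of 1 donor. There is no replicate, so no test was made, and every interval is a 95% interval of counting error alone.

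Of the 6456 barcodes, 1943 (30.1%, exact interval 29.0 to 31.2) were called Hashtag_1 and 2234 (34.6%, 33.4 to 35.8) Hashtag_2. Another 291 (4.51%, 4.01 to 5.04) carried both hashtags and 1988 (30.8%, 29.7 to 31.9) carried neither above its threshold. After removal of barcodes with fewer than 500 genes or over 10% mitochondrial UMIs, 1810 Hashtag_1 and 1966 Hashtag_2 cells were compared. Hashtag_2 cells held more RNA molecules, with a median of 13979 human gene UMIs per cell against 6026 in Hashtag_1, a ratio of 2.32 (1.79 with another hashtag caller, MULTIseqDemux). They also held more detected genes, 3713.5 against 2303.5. Mitochondrial UMIs took a median of 4.77% in Hashtag_1 and 4.89% in Hashtag_2 cells. Antibody UMIs differed less, with medians of 5801.5 and 6708.5. The summed depth was 12949879 human gene UMIs in Hashtag_1 and 32333538 in Hashtag_2.

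If each hashtag marked 1 culture, the comparison addresses how control and memory-like NK cells of the same donor differ, without a stated direction. Most CD56dim genes, which mark mature circulating NK cells, were higher in Hashtag_1 (13 of 15), while S phase genes, which copy DNA (18 of 18), and most MHC class II genes (7 of 9) were higher in Hashtag_2. Of 8508 genes with at least 10 CPM (UMIs of a gene scaled to the total of human gene UMIs) in either group, 787 were higher in Hashtag_2 and 1565 higher in Hashtag_1 by at least 1.5 times. At 2 times, the counts were 263 and 528. Of 24 gene lists, 8 had a median log2 ratio in the top 2.5% and 10 in the bottom 2.5% of 10000 random lists. The split depends on scaling: 33.5% of the genes past 1.5 times were higher in Hashtag_2 with CPM and 65.6% with TMM scaling (1538 against 806), which moved the median gene by 0.22 on the log2 scale. Without any scaling, as mean UMIs per cell, 8111 genes were higher in Hashtag_2 and 121 in Hashtag_1, and without the 4 clusters led by cell cycle or histone genes the CPM counts were 400 and 967.

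**Figure D1:**
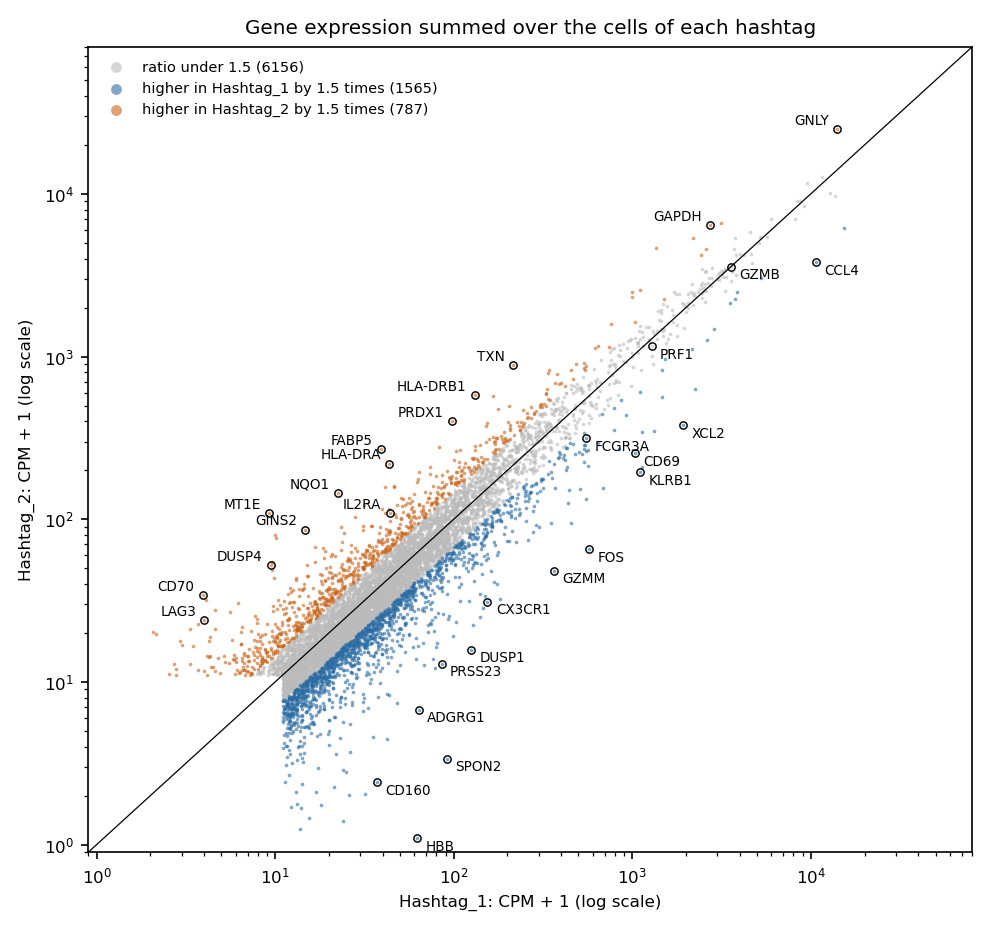
Expression of 8508 genes as CPM plus 1 (log axes) summed over 1810 Hashtag_1 cells (horizontal) and 1966 Hashtag_2 cells (vertical), 1 point per gene. The 787 orange genes were higher in Hashtag_2 and the 1565 blue genes higher in Hashtag_1 by at least 1.5 times with CPM (1538 and 806 with TMM scaling), and GZMB (3588 and 3560 CPM) lies on the line of equal values.

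Toward Hashtag_1, the secreted integrin ligand SPON2 (ENSG00000159674) had 90.4 CPM (85.3 to 95.8) in Hashtag_1 and 2.38 CPM (1.88 to 2.98) in Hashtag_2, a ratio of 37.97 (30.1 to 48.5). CD160, a receptor of cytotoxic lymphocytes, had 36.2 against 1.42 CPM, 25.5 times higher (18.8 to 35.3). The adhesion receptor gene ADGRG1, a marker of cytotoxic lymphocytes, was 10.9 times higher (9.32 to 12.9). The immediate early transcription factor FOS was at 573.8 and 64.5 CPM (8.90 times, 8.47 to 9.35), and the phosphatase DUSP1, another immediate early gene, at 123.8 and 14.8 CPM. GZMM, a granzyme protease, was at 364.3 and 47.2 CPM (7.72 times, 7.28 to 8.18). TCF7, a transcription factor of naive and memory lymphocytes, was at 77.5 and 11.1 CPM, and KLRB1, which encodes the inhibitory receptor CD161, at 1111 and 193.2 CPM. PRSS23, ICAM2, C1orf162 and LINC00861 were 5.76 to 7.10 times higher. These genes were lower in Hashtag_2 per cell as well, for example SPON2 with 0.647 and 0.0392 and FOS with 4.11 and 1.06 UMIs per cell. HBB, a haemoglobin gene, had 797 UMIs in Hashtag_1 and is among the largest ratios, but only 3 Hashtag_1 cells held any and 796 of the UMIs lay in cluster 8, so this is no difference between the groups as a whole.

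Toward Hashtag_2, the metal-binding metallothionein MT1E (ENSG00000169715) had 8.26 CPM (6.77 to 9.99) in Hashtag_1 and 107.7 CPM (104.2 to 111.4) in Hashtag_2, a ratio of 13.0 (10.8 to 16.0). HPGD, which breaks down prostaglandins, was 8.25 times higher (6.86 to 10.0), and FABP5, a fatty acid carrier, 7.11 times higher (6.49 to 7.80; 37.99 and 269.9 CPM). The quinone reductase NQO1 was at 21.5 and 144.4 CPM, the thioredoxin gene TXN at 214.4 and 880.6 CPM (4.11 times, 3.95 to 4.27) and the peroxiredoxin PRDX1 at 96.7 and 401.4 CPM. The replication factor GINS2 was 6.21 times higher (5.34 to 7.27). DPP4, the surface peptidase CD26, was 6.18 times and the phosphatase DUSP4 6.11 times higher; both log2 ratios were lower with MULTIseqDemux (1.90 and 1.89), and that of DPP4 was -0.06 among the barcodes HTODemux called negative. Those barcodes held medians of only 78 Hashtag_1 and 102 Hashtag_2 UMIs. They were split by MULTIseqDemux, so their assignment here and below is uncertain. The MHC class II genes HLA-DRA (ENSG00000204287) and HLA-DRB1 were 5.14 and 4.41 times higher, at 42.6 and 218.9 CPM and at 130.5 and 575.7 CPM. CD70, a costimulatory ligand, had 2.93 and 33.1 CPM, and LAG3, a checkpoint receptor, 3.01 and 22.9 CPM. IL2RA, the high-affinity subunit of the interleukin 2 receptor, was 2.54 times higher (2.32 to 2.78), at 42.7 and 108.3 CPM. Without the clusters led by cell cycle genes the log2 ratios shrank, for HPGD from 2.91 to 0.86, FABP5 from 2.80 to 1.28, PRDX1 from 2.04 to 0.47 and HLA-DRA from 2.34 to 0.73. HLA genes share sequence with close relatives and their counts are uncertain.

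All 18 measured S phase genes were higher in Hashtag_2 by at least 1.5 times with CPM, with a median log2 ratio of 1.33; examples are the helicase subunit MCM2 (19.5 and 58.5 CPM) and the nucleotide enzyme subunit RRM2 (62.4 and 176.4 CPM). Of 18 genes of G2 and mitosis, 7 were higher and 0 lower, with a median of 0.49. CDC20 was at 57.8 and 109.6 CPM and the kinase PLK1 at 56.4 and 98.3 CPM. MKI67, the proliferation marker Ki-67, was at 388.0 and 479.0 CPM, 1.23 times higher. Both medians lay in the top 2.5% of 10000 random lists of matched expression. TMM scaling and unscaled UMIs per cell shift ratios toward Hashtag_2, by 0.22 and 1.17 at the median gene. Neither could bring these medians below 0. Without the 4 clusters led by cell cycle or histone genes the S phase median was 0.53 and the G2 and mitosis median 0.905. These clusters were picked by genes of the same lists and histone genes, so both values depend on that selection. They held 21.8% of Hashtag_1 and 56.6% of Hashtag_2 cells. The G2 and mitosis median was 0.27, outside the top 2.5%, without the unnamed clusters described below. Among the barcodes HTODemux called negative, which are other cells, that median was -0.05.

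Of 18 genes of glycolysis and glucose uptake, 11 were higher in Hashtag_2 and 1 in Hashtag_1; GAPDH was 2.36 times, PKM 2.35 times and ENO1 2.08 times higher. Of 20 genes of oxidative phosphorylation, 6 were higher and 0 lower, among them NDUFS5, COX5A and ATP5MC3 with ratios of 1.73 to 1.84. Of 15 genes of amino acid uptake, synthesis and one-carbon metabolism, 9 were higher and 1 lower; the serine synthesis enzymes PSAT1 and PHGDH had 2.32 and 20.01 CPM and 5.56 and 20.7 CPM. The list medians were 0.74, 0.50 and 0.69 on the log2 scale, each in the top 2.5% of random lists. These medians also lay above 0 with TMM scaling and unscaled UMIs per cell, which shift ratios toward Hashtag_2 and could not turn them. They were 0.41, 0.26 and 0.23 without the clusters led by cell cycle genes and 0.32, 0.21 and 0.08 among the barcodes HTODemux called negative. The amino acid list left the top 2.5% among these barcodes and at a minimum of 50 CPM (median 0.32).

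MHC class II genes, which present peptides to helper T cells and which activated lymphocytes can express, were higher in Hashtag_2 for 7 of 9 measured members and lower for 0. Their median log2 ratio was 1.21, which both other scalings could only raise. It was 0.70 without the clusters led by cell cycle genes and 0.18 among the barcodes HTODemux called negative, where it left the top 2.5% of random lists. MHC class I and antigen processing genes pointed the other way with CPM, with 6 of 14 higher in Hashtag_1, 1 higher in Hashtag_2 and a median of -0.41, which was 0.70 with unscaled UMIs per cell. HLA-E, the ligand of the NKG2A receptor, was 2.61 times higher in Hashtag_1 (1474 and 564.3 CPM; 10.6 and 9.28 UMIs per cell). Of 21 interferon-stimulated genes, 11 were higher in Hashtag_1 and 0 in Hashtag_2, with a median of -0.66 (0.54 unscaled). The antiviral IFITM3 was 3.45 times higher in Hashtag_1 (3.15 to 3.78). However, 17.7% of its UMIs lay in 10 cells, which the interval does not cover. It was also among the top 10 genes of cluster 8, at 1483 CPM against 37.3 CPM in the other cells.

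Genes that mark CD56dim NK cells, the mature cytotoxic subset of blood, were higher in Hashtag_1 for 13 of 15 measured members and higher in Hashtag_2 for 0. Their median log2 ratio was -1.64, in the bottom 2.5% of random lists, and stayed below 0 with TMM scaling (-1.42) and with unscaled UMIs per cell (-0.47). Among the barcodes HTODemux called negative, which are other cells with an uncertain assignment, it was 0.03. FCGR3A, which encodes the antibody receptor CD16, was at 549.6 and 314.2 CPM, 1.75 times higher in Hashtag_1 (1.697 to 1.803), while its unscaled mean was higher in Hashtag_2 (3.93 and 5.17 UMIs per cell). Genes that mark CD56bright cells, the cytokine-producing subset, were mixed, with 6 of 13 higher in Hashtag_1, 1 higher in Hashtag_2 and a median of -0.29 (0.87 unscaled, and 0.19 without the clusters led by cell cycle genes). This list entered the bottom 2.5% of random lists in 7 of 21 alternatives, for example with MULTIseqDemux (-0.45) and the stricter filter (-0.65). NCAM1, which encodes CD56 itself, was 1.22 times higher in Hashtag_2 (1.15 to 1.30).

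Of 20 activating receptors and adaptors, 12 were higher in Hashtag_1 and 1 in Hashtag_2, with a median log2 ratio of -0.73 that turned to 0.45 with unscaled UMIs per cell. KLRF1, the activating receptor NKp80, was at 260.3 and 73.8 CPM and CRTAM, an adhesion receptor, at 71.0 and 19.1 CPM. Of 17 inhibitory and checkpoint receptors, 12 were higher in Hashtag_1 and 1, LAG3, in Hashtag_2, with a median of -1.06 (0.13 unscaled). Among the barcodes HTODemux called negative both medians left the bottom 2.5% of random lists, at -0.08 for activating and -0.12 for inhibitory receptors. KIR3DL2, a receptor for MHC class I, was 5.23 times higher in Hashtag_1 (4.83 to 5.67), and KLRC1, which encodes NKG2A, was about equal at 478.2 and 474.5 CPM. Of 15 cytokine receptors, 6 were higher in Hashtag_1 and 1, IL2RA, in Hashtag_2, with a median of -0.39 (0.80 unscaled) that left the bottom 2.5% in 4 alternatives, with -0.10 without the clusters led by cell cycle genes; IFNGR1, IL21R and TGFBR2 were 2.55 to 3.10 times higher in Hashtag_1. KIR genes are near-identical copies of each other, and their counts are uncertain.

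XCL1 and XCL2, which attract dendritic cells, were 5.42 times (5.27 to 5.58) and 5.08 times (4.97 to 5.19) higher in Hashtag_1, and CCL4, which attracts T cells and monocytes, 2.80 times higher (10680 and 3810 CPM). IFNG, the main NK cytokine, went the other way at 66.1 and 115.4 CPM, 1.75 times higher in Hashtag_2 (1.62 to 1.88). Across 14 cytokines and chemokines, 6 were higher in Hashtag_1 and 1 in Hashtag_2, with a median log2 ratio of -0.53 (0.67 unscaled; -0.14 and outside the bottom 2.5% of random lists without the clusters led by cell cycle genes). With equal weight per cell this median was -0.27, also outside the bottom 2.5%. Of 18 cytotoxic effectors, 14 were within 1.5 times. The granule protease GZMB was at 3588 and 3560 CPM and the pore protein PRF1 at 1285 and 1153 CPM, while GNLY, which lyses microbes, was at 14020 and 25070 CPM, 1.79 times higher in Hashtag_2 (1.779 to 1.797). The cytotoxic median was -0.18 with CPM, 0.05 with TMM scaling, 1.01 unscaled and 0.12 without the clusters led by cell cycle genes. XCL1 and XCL2, like CCL4 and its relatives, are close copies, and their counts are uncertain.

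Of 30 measured transcription factors, 17 were higher in Hashtag_1 and 1 in Hashtag_2, with a median log2 ratio of -0.71 (0.48 unscaled). The nuclear receptors NR4A1 and NR4A2, induced by receptor signalling, were 5.56 and 5.11 times higher in Hashtag_1. Of 17 stress and immediate early genes, 8 were higher in Hashtag_1 and 2 in Hashtag_2, with a median of -0.47 (0.90 unscaled, -0.82 at a minimum of 50 CPM, and -0.09 and outside the bottom 2.5% with no minimum); JUN, the partner of FOS, was at 101.8 and 22.4 CPM. Genes of homing and adhesion were split, with 7 of 20 higher in Hashtag_1 and 5 in Hashtag_2 and a median of -0.17 with CPM, 0.05 with TMM scaling, 1.19 unscaled and 0.15 without the clusters led by cell cycle genes. That list entered the bottom 2.5% of random lists at a minimum of 50 CPM (-0.405) and among the barcodes HTODemux called negative (-0.168). It entered the top 2.5% without the clusters led by cell cycle genes. CX3CR1, the fractalkine receptor of mature NK cells, was 5.10 times (4.73 to 5.52) and CD69, an early activation marker, 4.11 times (3.99 to 4.22) higher in Hashtag_1, while ITGA1, a collagen receptor subunit, had 1.78 and 11.1 CPM.

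**Figure D2:**
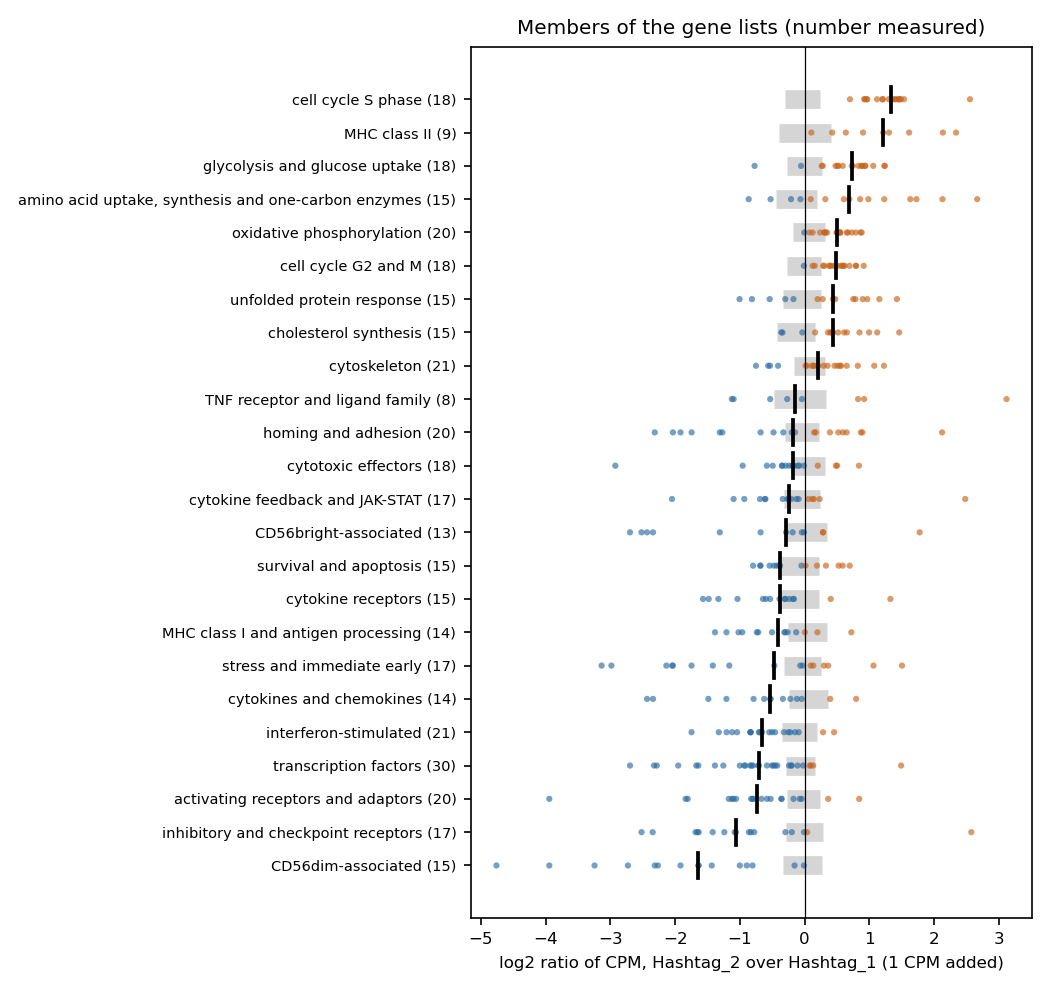
Log2 ratio of CPM, Hashtag_2 over Hashtag_1 with 1 CPM added, for each measured member (points) of the 24 gene lists, with the list median (black bar) and the middle 95% of 10000 random lists of matched expression (grey). The medians run from -1.64 for CD56dim genes to 1.33 for S phase genes; with unscaled UMIs per cell 23 of 24 lie above 0, and with TMM scaling the cytotoxic, homing and TNF family medians also turn above 0.

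To compare shares of cells at equal depth, each cell was thinned to 2724 UMIs, leaving out 179 Hashtag_1 and 85 Hashtag_2 cells that held fewer. A UMI of CD69 was found in 85.9% (84.1 to 87.6) of 1631 thinned Hashtag_1 and 44.1% (41.8 to 46.4) of 1881 thinned Hashtag_2 cells (unthinned 93.7% and 82.1%). SPON2 was found in 20.1% (18.2 to 22.1) and 0.744% (0.408 to 1.246; unthinned 32.5% and 3.41%). TXN was found in 37.95% (35.6 to 40.4) and 80.0% (78.1 to 81.8; unthinned 64.5% and 96.1%), HLA-DRA in 5.76% (4.68 to 7.01) and 24.1% (22.2 to 26.1; unthinned 12.9% and 47.2%), and IL2RA in 8.71% (7.38 to 10.2) and 21.4% (19.6 to 23.4; unthinned 18.6% and 63.3%). MKI67 was found in 24.8% (22.8 to 27.0) and 45.6% (43.3 to 47.8; unthinned 28.6% and 63.6%). As background, barcodes with at least 95% mouse UMIs thinned to the same depth held CD69, SPON2, TXN, HLA-DRA and IL2RA in 0 of 90, which allows up to 4.02%, and MKI67 in 2.22%. The SPON2 share of Hashtag_2 cells lies below that limit and is not told from background, and GNLY reached 24.4% of these 90 barcodes.

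On the cell surface, Hashtag_2 cells carried more HLA-DR and CD25 and Hashtag_1 cells more CD45RA. HLA-DR, the MHC class II protein, had a mean of 51.6 UMIs per cell in Hashtag_1 and 780.5 in Hashtag_2, a ratio of 13.8 after scaling by total antibody UMIs. CD25, the protein of IL2RA, had means of 65.6 and 531.4 (7.41 times). CD45RO, the CD45 form of activated and memory lymphocytes, had means of 18.9 and 150.2 (7.27 times), and the form of resting cells, CD45RA, 2138 and 416.4, 5.62 times higher in Hashtag_1. Medians were 29 and 162 for HLA-DR (5.59 times), 50 and 200 for CD25 (4 times), 15 and 83 for CD45RO (5.53 times) and 1780 and 192 for CD45RA. The share of cells above the 99th percentile of the highest isotype control was 19.5% (17.7 to 21.4) and 62.8% (60.6 to 64.9) for HLA-DR, 50.3% (48.0 to 52.7) and 92.5% (91.3 to 93.7) for CD25, and 3.09% (2.345 to 3.999) and 53.0% (50.8 to 55.2) for CD45RO. Isotype controls summed to 32.6 and 41.3 UMIs per cell.

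Of the proteins other than the 3 isotype controls, 8 were higher in each group by at least 1.5 times after scaling. CD45RA weighed unequally in the scaling total, with 3869525 of 12863567 antibody UMIs in Hashtag_1 and 818691 of 15281184 in Hashtag_2. The ratio of mean antibody UMIs per cell was 1.09 with all antibodies and 1.48 without CD45RA. A total without CD45RA would lower all ratios toward Hashtag_2 and was not used for scaling. CD94, at 1.505, would then fall below 1.5, so the count of 8 toward Hashtag_2 depends on the total chosen. Scaling by the isotype controls left 6 proteins higher in Hashtag_2 and 8 in Hashtag_1. The activating receptor CD314 (NKG2D) was 2.07 times, CD56 1.91 times and the inhibitory receptor NKG2A 1.76 times higher in Hashtag_2. The KIR proteins KIR3DL1, KIR2DL1_S1_S3_S5 and KIR2DL2_3 were 2.31, 2.16 and 1.62 times higher in Hashtag_1. CD117 (the stem cell factor receptor KIT) was 2.15 times higher there, CD57, a marker of terminal maturation, 2.002 times and CD16 1.59 times. Some medians differed little, at 11.0 UMIs in both groups for KIR2DL1_S1_S3_S5, 14.0 and 13.0 for KIR3DL1 and 13.0 and 10.0 for CD117. For KIR2DL1_S1_S3_S5, 17.7% (15.9 to 19.5) and 5.34% (4.39 to 6.43) of cells were above the isotype threshold. Without scaling, 5 proteins were higher in Hashtag_1 by 1.5 times, and KIR2DL2_3 and CD16 were below that size at 1.48 and 1.46.

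**Figure D3:**
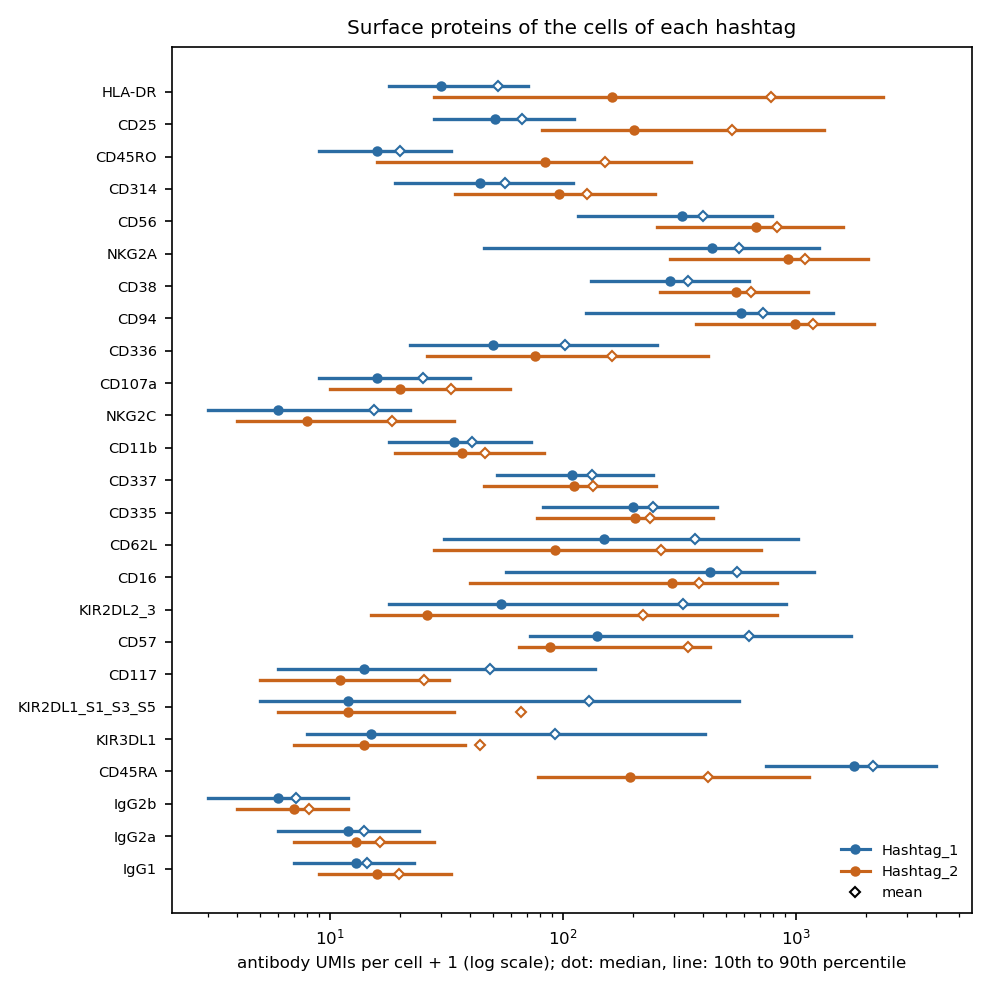
Antibody UMIs per cell plus 1 (log axis) of surface proteins and 3 isotype controls (IgG1, IgG2a, IgG2b) in Hashtag_1 (blue) and Hashtag_2 (orange) cells, with dots for medians, diamonds for means and lines from the 10th to the 90th percentile of cells. Mean HLA-DR was 51.6 and 780.5 and mean CD45RA 2138 and 416.4 UMIs per cell.

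RNA and protein could be paired for 17 targets. Across these pairs, which are not independent replicates, the log2 ratios of gene and protein had a Spearman rho of 0.62 (0.55 to 0.79 with each pair left out in turn). HLA-DR with HLA-DRA, CD25 with IL2RA and CD56 with NCAM1 were higher in Hashtag_2 on both levels, and CD16 with FCGR3A was higher in Hashtag_1 on both after scaling, although FCGR3A was not in unscaled UMIs per cell. With CPM and scaled proteins the signs were opposite in 6 pairs, among them NKG2A, whose gene was about equal; with both unscaled per cell they were opposite in 4. Among the 6, named after their values were seen, CD314 was 2.07 times higher in Hashtag_2 and its gene KLRK1 had 42.5 and 18.3 CPM, or 0.304 and 0.301 UMIs per cell. CD94 was 1.51 times higher in Hashtag_2 (1.30 with isotype scaling) and its gene KLRD1 had 918.9 and 434.2 CPM, or 6.58 and 7.14 UMIs per cell.

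Clustering at a resolution of 0.6 gave 9 clusters, and in clusters 0 to 6 all 14 NK markers were detected in at least 25% of cells, and all but cluster 3 of these were called NK-like. Cluster 3 (390 cells) stayed unnamed because KIT, an innate lymphoid marker, was among its top 10 genes. No cluster had an NK marker there, and the mean log2 ratio of NK markers in cluster 3 was 0.25 against the other cells. Clusters 7 (103 cells, median 1778 UMIs) and 8 (8 cells) stayed unnamed as well. Clusters 3, 7 and 8 held 17.1%, 0.718% and 0.221% of Hashtag_1 and 4.12%, 4.58% and 0.203% of Hashtag_2 cells. As genes that lead cluster 3, such as XCL1, differ between the groups, these shares were not compared. Most NK-like clusters were mainly of a single hashtag, with 1047 Hashtag_1 and 45 Hashtag_2 cells in cluster 0, 42 and 633 in cluster 1 and 12 and 373 in cluster 4. Clusters 5 (52 and 201) and 6 (17 and 207) were also mostly Hashtag_2, while cluster 2 held 314 and 332. The NK-like cells of the groups were compared only as a whole. At a resolution of 1.0, a cluster of 80 cells had a mean log2 ratio of 1.14 for other innate lymphoid markers. The summed CPM of NK markers was 34300 in Hashtag_1 and 42860 in Hashtag_2, of which GNLY alone made up 14020 and 25070, and 4 of the 14 markers were higher in Hashtag_1 and 1 in Hashtag_2. Markers of other cells were low, with T cell markers at 252.5 and 136.7, B or plasma cell markers at 48.2 and 34.7 and monocyte or macrophage markers at 61.0 and 48.5. Dendritic cell markers stood at 3.32 and 4.24, platelet markers at 2.01 and 0.650 and other innate lymphoid markers at 35.3 and 22.1. Erythroid markers stood at 67.0 and 0.0928, nearly all of it HBB of cluster 8.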

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

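The tests on mouse barcodes and the test of empty droplets were chosen only after the result was seen; the test of barcodes without a called hashtag against the called cells was set before.

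Mouse genes lie outside the comparison, yet 152 of the 6456 barcodes (2.35%, 1.998 to 2.754) held mostly mouse UMIs, with a median of 3114 mouse and 20.5 human UMIs. In the kept Hashtag_1 cells a median of 0.339% of UMIs were mouse, which argues against human reads aligned to mouse genes as the whole cause, since such reads would arise in human cells too. All 152 held at least 10 hashtag UMIs (lowest 24). This argues against gene reads alone carried over from another library at the sequencer, since a borrowed barcode need not match a droplet with hashtags. Their medians were 21 Hashtag_1 and 57.5 Hashtag_2 UMIs, against 17 and 36 for the hashtag not called in kept cells. A background of hashtags thus passes the limit of 10, and carry-over of hashtag reads as well was not tested. HTODemux called 123 of them negative, and 5 passed the cell filter. Mouse cells in the same capture may be a source and were not tested; no group of the design gives a biological explanation.

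Of the 5566 barcodes that passed the cell filter, 1524 (27.4%, 26.2 to 28.6) had no called hashtag and entered no comparison, although they held a median of 6147.5 human UMIs. As the filter removes shallow barcodes, empty droplets were tested on all 1988 barcodes with no called hashtag, whose median of 3798.5 (3307 to 4472, bootstrap over barcodes) was over 50% of the 5684 of Hashtag_1 barcodes before the filter, which argues against empty droplets or debris as the whole cause, while 24.3% held under 1000. MULTIseqDemux assigned 623 of the 1524 to Hashtag_1 and 566 to Hashtag_2, and the log2 ratios between these followed those of the called cells across genes with a Spearman rho of 0.56. This lies between the 0.8 and 0.3 that would have decided whether they are cells of the same cultures with few hashtag UMIs, so that and a mixed assignment cannot be told apart. The culture condition was not tested, since the hashtags are not tied to it.

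Barcodes with mostly mitochondrial UMIs, which the filter removes, numbered 346 (5.36%, 4.82 to 5.94), with a median of 881 human UMIs.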

How the results depend on the processing

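Chosen only after the results were seen were the tests with unscaled UMIs per cell, without barcodes with mouse UMIs, without cell cycle clusters, without clusters 7 and 8 alone, without the highest Scrublet scores, with HTODemux-negative barcodes alone and with shares above isotype background. Over 21 alternatives for 87 of the 89 genes the rule named, 1180 values stayed within counting error, 632 moved further and 15 turned, which counts only genes past 1.5 times with all cells; at any size 38 changed sign. Omission of Scrublet calls, use of the other matrix and both other CPM minimums cannot change a gene's own ratio, so 348 of the 1180 say nothing about stability. Genes higher in Hashtag_2 and Hashtag_1 numbered 1538 and 806 with TMM scaling, 8111 and 121 unscaled, 393 and 512 at a minimum of 50 CPM and 3672 and 5876 with none (fewer or more genes are counted), 400 and 967 without cell cycle clusters, and 496 and 646 among HTODemux-negative barcodes, where 3 lists lay in the top 2.5% and activating and inhibitory receptor, CD56dim, G2 and mitosis, amino acid, cholesterol, MHC class II, survival and unfolded protein lists left the outer 2.5%. Unscaled means brought 14 list medians from below to above 0; past the 1.5-times size with all cells were those of activating receptors (0.45), inhibitory and checkpoint receptors (0.13), transcription factors (0.48) and interferon-stimulated genes (0.54). They also turned the genes TNFRSF4 (0.059), MCL1 (0.51), FCGR3A (0.39), HLA-F (0.17), DNAJB9 (0.11), BCL2A1 (0.39), STAT3 (0.088), CST7 (0.24) and TNFSF14 (0.069); the deeper Hashtag_2 cells produce this shift by construction. Among HTODemux-negative barcodes the CD56dim median (0.034) and FCGR3A (0.067), DPP4 (-0.057), MTHFD1L (-0.16), PLK1 (-0.20) and AURKA (-0.065) turned, and without cell cycle clusters BCL2A1 (0.012); the cause was not tested. Without cell cycle clusters, 4 list medians below 0 lay above it (cytotoxic, TNF family, CD56bright and homing genes), none past the 1.5-times size; cytokine, cytokine receptor, survival and unfolded protein lists left the outer 2.5%, homing and cytoskeleton lists entered the top, and 34 of the 87 genes moved by at least 1.5 times (86 unscaled, 52 among HTODemux-negative barcodes, 19 with a pseudocount of 10 CPM, at most 7 otherwise); the S phase median, 1.33 with all cells, was 0.53 and the G2 and mitosis median, 0.49 with all cells, 0.905, and the cause was not tested. Proteins higher in Hashtag_1 numbered 5 unscaled and 4 by medians, and those higher in Hashtag_2 numbered 4 by the share above isotype, where the log2 ratios of CD56 (-0.004) and CD94 (-0.003) turned because nearly all cells of both groups pass; the cause of the other moves was not tested. The ratio of median UMIs was 1.79 with MULTIseqDemux, 1.81 with the margin rule, 2.16 without a cell filter and 2.58 with the stricter filter. Hashtag_2 made up 52.1% of compared cells, 58.2% with the margin rule and 50.2% with the stricter filter. CD94 was under 1.5 times with MULTIseqDemux, the margin rule and isotype scaling, CD38 with isotype scaling, and CD16 and KIR2DL2_3 with MULTIseqDemux. Resolution 0.3 gave 5 clusters in place of 9. Depth limits low genes: 3 UMIs are 0.232 CPM in Hashtag_1 and 0.0928 in Hashtag_2. No paired analysis was possible because there is 1 sample.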

Other observations

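The tests of doublets and of cell cycle below were chosen only after the result was seen; the test of the hashtag threshold was set before.

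Further gene groups were split between the hashtags. Of 15 genes of the unfolded protein response, which helps proteins fold in the endoplasmic reticulum, 6 were higher in Hashtag_2 and 2 in Hashtag_1, with a median log2 ratio of 0.44 (-0.01 among the barcodes HTODemux called negative, and 0.05 and outside the top 2.5% of random lists without the clusters led by cell cycle genes); the chaperone CALR was 2.69 times higher in Hashtag_2 (2.58 to 2.82). With equal weight per cell the median of this list was 0.19, also outside the top 2.5%. Of 15 genes of cholesterol synthesis, 6 were higher in Hashtag_2 and 0 in Hashtag_1, with a median of 0.44; an example is SQLE (26.02 and 52.8 CPM). Of 21 cytoskeleton genes, 4 were higher in Hashtag_2 and 1 in Hashtag_1, with a median of 0.21; TMSB10, which binds actin monomers, was 2.11 times and the galectin LGALS1 2.34 times higher in Hashtag_2. TMM scaling and unscaled UMIs per cell shift ratios toward Hashtag_2, so they could not turn these 3 medians below 0.

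Of 15 survival genes, 3 were higher in Hashtag_1 and 2 in Hashtag_2, with a median of -0.38 that was 0.90 with unscaled UMIs per cell and left the bottom 2.5% of random lists in 12 of 21 alternatives; MCL1, which protects cells from apoptosis, had 176.4 and 109.4 CPM and 1.26 and 1.799 UMIs per cell. Of 17 genes of JAK-STAT feedback, 6 were higher in Hashtag_1 and 1, DUSP4, in Hashtag_2, with a median of -0.25 (0.92 unscaled). The phosphatase DUSP2 was 4.16 times higher in Hashtag_1 (4.003 to 4.32). Of 8 genes of the TNF family, 3 were higher in Hashtag_2, among them CD70, and 2 in Hashtag_1, with a median of -0.16 with CPM, 0.07 with TMM scaling, 1.15 unscaled and 0.16 without the clusters led by cell cycle genes. The 8 cells of cluster 8 were 4 of each hashtag. Summed over them, HBD stood at 3797 CPM and GATA2 at 323.7 CPM, each with a UMI in 87.5% of the cells, and HBB at 4691 CPM (37.5% of the cells), PRG2 at 753.4 CPM (25%) and CLC at 447.4 CPM (12.5%) came from fewer. These cells had a median of 22.5 CD56 antibody UMIs against 481.0 in the other kept cells.

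Hashtag_2 cells held 2.32 times as many UMIs at the median as Hashtag_1 cells. Doublets within Hashtag_2 would raise antibody UMIs alike if cells carry similar amounts of protein. The ratio of mean antibody UMIs per cell was 1.09 (bootstrap over the cells of this library 1.05 to 1.14) with all antibodies. It was 1.48 (1.42 to 1.54) without CD45RA. The second value is under the limit of 1.5 set for this test, but its interval passes that limit, so doublets stay open. This test replaced one on doublets of both hashtags after both values were seen. More cells in cycle are argued against as the whole cause by a ratio of 1.65 (1.49 to 1.81) among cells with no UMI of 36 cell cycle genes after thinning. That ratio is below the 2.32 of all cells, and it was 1.82 without the clusters led by cell cycle genes, so cycling may add a part. A hashtag threshold that selects large cells is argued against as the whole cause by a ratio of 1.81 (1.73 to 1.90) under the margin rule, but the ratio was 0.971 among barcodes that HTODemux called negative, so it may add a part. A difference between the cultures stays open, untested.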
